A study of Mus musculus with 8 samples.

How the data were processed

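RNA from 8 mouse liver samples was labelled with Cy3, per the labels' protocols, and each sample was hybridised to 1 Agilent array of 62976 spots. All 8 arrays lay on 1 slide and came from 1 scan. The wild-type arrays filled 1 column of the slide and the knockout arrays the other, so slide column and genotype cannot be told apart. The authors deposited the scanner output of Agilent Feature Extraction 10.10, per the submitters' processing notes, which give spot intensity (processed, mean, median and background signals) on a linear scale. The deposited value table is in log2 units. Its columns followed the log2 median signal of the same array, taken before normalization (r from 0.99995 to 0.999994), with no centring of genes, and their medians ran from 8.84 to 8.86. It holds 27084 probes.

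The main values were log2 of the processed signal minus the array's 75th percentile over non-control probes. Control spots and outlier-flagged spots were left out, and spots of 1 probe were averaged. Probes flagged on all spots of an array (87) were left out. A probe was kept if it was well above background on at least 4 of the 8 arrays, and each gene was represented by the kept probe with the highest mean over all arrays. No spot was saturated. Gene names were updated through the unversioned accession for 27235 of 55681 probes and through a unique synonym for 565, using a RefSeq table of assembly GRCm38.p6 for names only. Coordinates are those of the array files, on mm9 per the file headers. For called genes, no other kept probe of the gene went the opposite way at an unadjusted p under 0.05.

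Groups were compared with limma 3.58.1 (lmFit and eBayes, R 4.3.3) on all 8 arrays without covariates, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Lists were tested with camera at a preset correlation of 0.01, with an estimated correlation and with fry. Domain probes were also tested by an exact permutation test over 70 assignments. Genes named in the text were the 12 largest rises and falls among called genes with complete separation of the groups and a gene symbol (6 rises passed), up to 4 members of each list with the smallest p, and a fixed set: Mirg, Rian, Meg3, Dlk1, Rtl1, Dio3, Pck1, G6pc, Fbp1, Ppargc1a, Cpt1a, Fgf21, Igfbp1, Afp, Alb, Xist and Ddx3y. Another gene of that set is not reported here. These rules, the lists, the design and most alternatives were fixed before the data were examined. On simulated arrays with the real means and spreads, 4 per group, the knockout vs wild-type test recovered 33.4%, 77.9% and 95.2% of genes changed by 0.5, 1 and 2 log2 among 23526 genes, with 5.00% of calls on unchanged genes. That simulation drew independent arrays.

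After the data were examined, replicate 4 of each group was found to be close to a weighted sum of other arrays of its group. The design was kept as fixed, and a fit without both replicate 4 arrays (3 per group) was added and is given beside the counts of genes, domain probes and lists called, and beside the members called in the lists that fry called. Weights that sum to 1 were found by least squares on the log2 scale. Other alternatives were the normalization, background correction, signal column, filter, probe rule, variance model, Ddx3y or Xist as a covariate, the replicate number as a block, stricter thresholds, and leaving out arrays. The planned test of genes with matches to microRNA seeds was not run, because 3' UTR sequences were not used here.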

Results

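Liver gene expression was measured on 8 single-colour microarrays, 4 from wild-type mice and 4 from littermates lacking the miR-379/miR-410 microRNA cluster on the chromosome received from the mother (called knockout here). The pups were delivered by caesarean section at E19.5 and killed 4 h later. The cluster lies in the imprinted Dlk1-Dio3 domain, where the noncoding RNAs and microRNAs are made from the maternal chromosome. Between 58.6% and 66.2% of the spots of an array were well above background. After filtering, 23526 genes were tested. Levels are log2 signals relative to the array's 75th percentile, given as mean ± SD over arrays. Differences are knockout minus wild-type with their standard error (SE). The number of arrays limits the precision, and the median 95% interval of a difference was 0.26 wide on either side.

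The series description gives 4 biological replicates per genotype, but replicate 4 of each group could not be shown to be independent of the others. Xist, which is transcribed from the inactive X chromosome of females, and the Y-linked gene Ddx3y were both well above background in knockout 4. Xist there stood at 29.5% of the mean of knockout 1 and 2, and Ddx3y at 71.2% of knockout 3. In wild-type 4, Ddx3y stood at 56.6% of the mean of wild-type 1 and 2, with Xist not well above background. Weighted sums of the other 3 arrays of the group were fitted on 22631 genes outside the sex chromosomes and the pancreas list. The weights were 0.43 for wild-type 2 and 0.50 for wild-type 3 in the case of wild-type 4, and 0.35 for knockout 2 and 0.65 for knockout 3 in the case of knockout 4. These weights predicted the sex-linked probes with a median absolute error of 0.13 log2 in wild-type 4 (3 probes) and 0.14 in knockout 4 (5 probes), against 0.56 to 9.37 when each of the other 6 arrays was predicted in the same way. Wild-type 3, knockout 1 and knockout 2 lacked Y-linked signal, which sums that include arrays with it cannot match. The errors of wild-type 1, wild-type 2 and knockout 3 were 0.59, 1.04 and 0.56. Over the pancreas probes the errors were 0.17 in wild-type 4 and 0.02 in knockout 4. They were 0.19 to 0.37 in the other knockout arrays and 1.61 to 4.15 in the other wild-type arrays. The p-values from 8 arrays below treat replicate 4 as independent and are too small if it is not. Results from the 6 other arrays, 3 per group, are therefore given beside them.

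**Figure D1:**
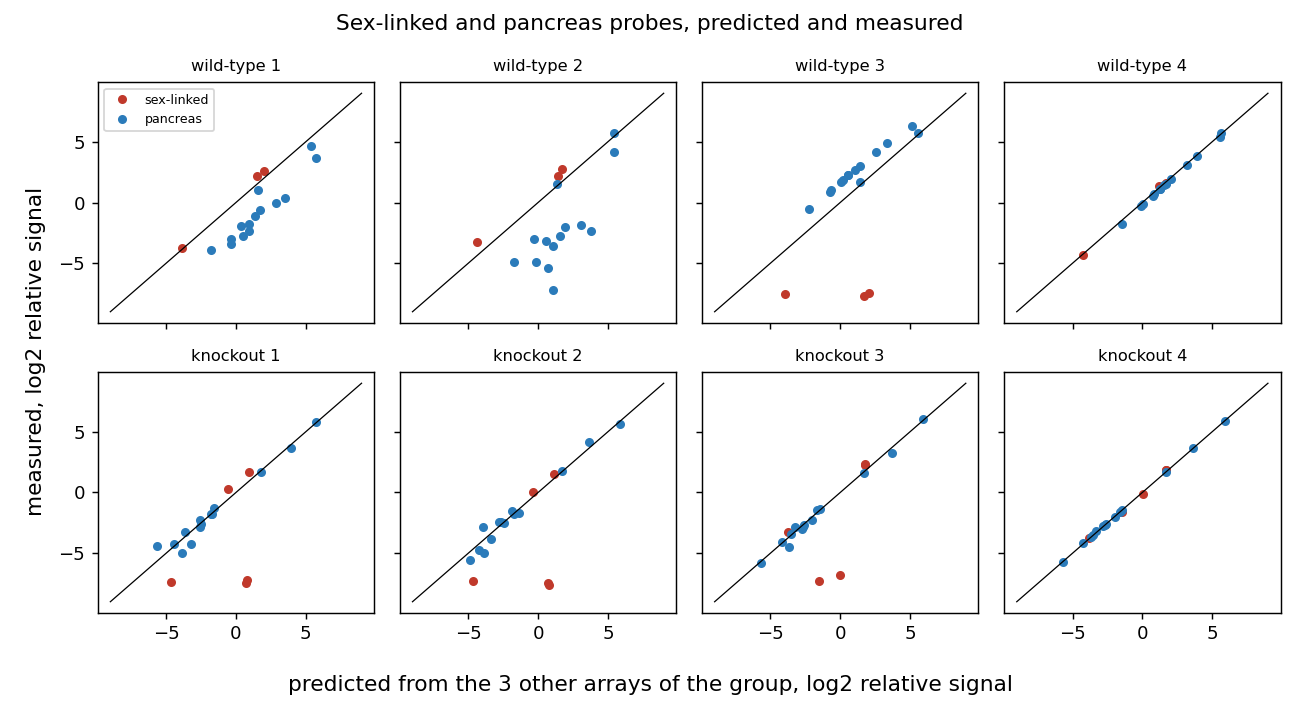
Measured against predicted log2 relative signal of sex-linked (red) and pancreas (blue) probes, 1 panel per array; the line marks equality, and predictions are weighted sums of the 3 other arrays of the group with weights fitted on other genes. Median absolute errors over the sex-linked probes were 0.13 in wild-type 4 and 0.14 in knockout 4, and 0.56 or more in each of the other 6 arrays.

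The first comparison checked the genotype at the deleted locus. Mirg, a noncoding RNA of the microRNA-rich part of the domain, had a level of 2.16 ± 0.06 in wild-type and -0.54 ± 0.33 in knockout livers (n = 4 arrays each). Its difference was -2.70 (SE 0.15, limma adjusted p = 0.000326), and it was still well above background on every knockout array. The other Mirg probe differed by -2.58. Without replicate 4 the difference of Mirg was -2.64 (limma adjusted p = 0.0230). Both Mirg probes separated the groups completely (two-sided exact permutation p = 0.0286, the smallest that 70 assignments of 8 arrays can give). The limits of the deletion were not given in the sources used here, so whether these probes lie inside it was not determined.

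Along chromosome 12 (mm9), 17 kept probes had starts between 110979653 and 110987569, the span of the Mirg probes. All 17 had lower means in knockout and 16 fell after adjustment over the 64 probes of the region and 11 after adjustment over all kept probes. Their median difference was -1.72. Of the 34 probes from Meg3 (first start 110782745) up to 110970826, 30 had higher means in knockout, with a median difference of 0.36, and 9 rose after adjustment over the region and 1 over all kept probes. With 6 arrays the medians were -1.60 and 0.39. In the Mirg interval 15 probes then fell over the region and 6 over all kept probes, and in the other part 5 rose over the region and 0 over all kept probes. The 7 probes on the Dlk1 side all had higher means in knockout, with a median of 0.25, and 2 rose over the region and 0 over all kept probes. With 6 arrays 6 of them were higher and 1 rose over the region. Of the 6 probes on the Dio3 side 3 were higher, with a median of -0.06, and none was called. Meg3, a maternally expressed noncoding RNA, stood at 5.61 ± 0.08 in wild-type and 6.04 ± 0.11 in knockout livers. Its difference of 0.43 did not pass over all genes (limma adjusted p = 0.0866). Dlk1, a paternally expressed growth regulator, differed by 0.25 (adjusted p = 0.407) and Dio3, a deiodinase, by 0.10 (adjusted p = 0.856), both by limma. The only Rtl1 probe was not well above background on any array, and Rian was not measured under that name.

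**Figure D2:**
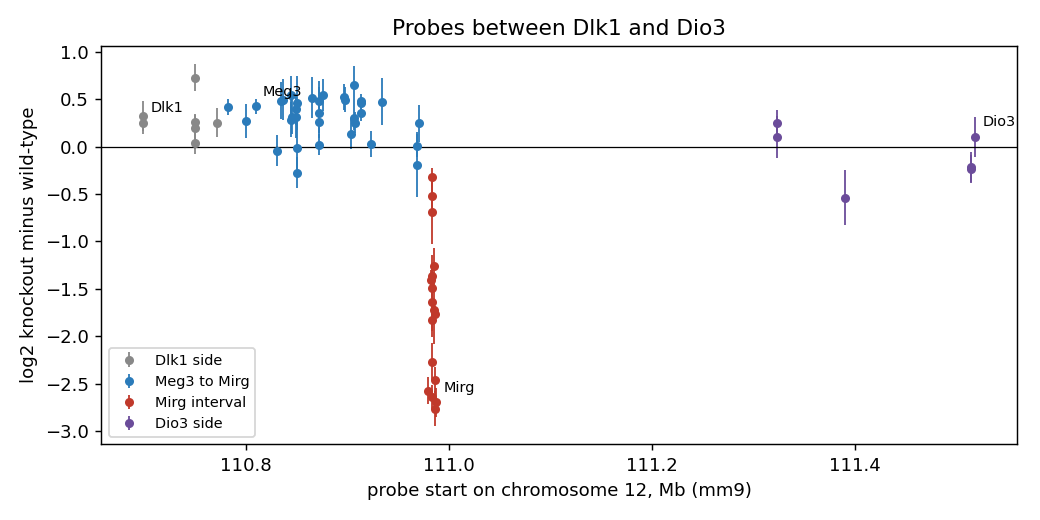
Knockout minus wild-type log2 difference of each kept probe between Dlk1 and Dio3, plotted by probe start in Mb on chromosome 12 (mm9), with SE bars. The 17 probes of the Mirg interval lie below 0, with a median of -1.72, and 30 of the 34 probes from Meg3 to that interval lie above 0.

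Over all genes, 42 were lower and 9 higher in knockout livers at a limma adjusted p under 0.05, with all 8 arrays. Without replicate 4 of both groups, 6 were lower and 0 higher, and 1724 genes had an unadjusted p under 0.05. These 6 were Mirg, a noncoding transcript that overlaps it, Cfc1, Akr1c6, Slco1b2 and Abcg5. All 51 genes kept their direction there, which was certain because each of them separated the groups completely. Leaving out 1 array at a time gave 14 to 66 lower and 0 to 24 higher. Xist was well above background on 3 knockout arrays and on no wild-type array, so sex and genotype partly coincide. With Xist as a covariate 8 of the 51 genes passed, and with Ddx3y as a covariate 45 did. Unequal sexes therefore stay open for these calls. Akr1c6, a hydroxysteroid dehydrogenase of the aldo-keto reductase family, fell from 3.74 ± 0.14 to 1.93 ± 0.11. Slco1b2, a hepatocyte uptake transporter for organic anions and bile acids, fell from 4.98 ± 0.09 to 3.54 ± 0.12. Abcg5, which forms a sterol exporter with Abcg8, fell from 1.97 ± 0.15 to 0.25 ± 0.18. Cfc1, a Nodal co-receptor, was not well above background on any knockout array and was at least 5.42-fold lower there. This bound sets the wild-type mean against the lowest signals that were well above background on the knockout arrays, on the main scale. The log2 difference of Cfc1 was -0.98 with normexp and quantile normalization together and -1.41 in the deposited value table, both smaller than that bound (limma adjusted p = 0.00704 and 0.00797).

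The other named falls passed with 8 arrays and did not pass with 6, where their differences ran from -1.53 (Ifi44) to -3.35 (Cyp2e1). Cyp2e1, a cytochrome P450 that switches on in the liver around birth, fell from 6.37 ± 0.61 to 3.15 ± 0.32 (limma adjusted p = 0.00502, and 0.105 with 6 arrays). Hsd17b6, a steroid-metabolising enzyme, differed by -2.21 (SE 0.17), and the carboxylesterases Ces3b and Ces3a by -2.14 (SE 0.16) and -2.02 (SE 0.20). Myl1, a muscle myosin light chain, differed by -3.27 (SE 0.42), Ptprz1, a receptor phosphatase, by -1.61 (SE 0.24), and Ifi44, an interferon-induced gene, by -1.53 (SE 0.20). With normexp and quantile normalization together Myl1 differed by -1.69 and Ptprz1 by -0.38, and both passed. Among the 6 named genes that were higher with 8 arrays and none of which passed with 6, Aqp3, a water and glycerol channel, differed by 0.91 (SE 0.11), Klhl1 by 0.91 (SE 0.13), Dnah17 by 0.81 (SE 0.11), Rnu3b1 by 0.63 (SE 0.09) and Spata17 by 0.56 (SE 0.08). With normexp and quantile normalization together Klhl1 differed by 0.47 and passed. Spata17 did not pass with normexp and quantile normalization together (0.12, limma adjusted p = 0.303) or in the deposited value table (0.14, limma adjusted p = 0.344). Tcp10b was not well above background on any wild-type array and was at least 1.72-fold higher in knockout livers on the main scale. With normexp and quantile normalization together its log2 difference was 0.25, under that bound, and did not pass (limma adjusted p = 0.0772), and in the deposited value table it was 0.43 (limma adjusted p = 0.0494).

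The named genes of glucose output and fatty acid use, which newborns need once the placental supply ends, did not pass the main test singly. Pck1, the enzyme that commits carbon to gluconeogenesis, differed by -0.43 (SE 0.11, limma adjusted p = 0.156), and passed when normexp background correction and quantile normalization were used together (-0.48, limma adjusted p = 0.0459). G6pc, which releases free glucose, differed by 0.05 (SE 0.17) and Fbp1 by -0.09 (SE 0.07). Ppargc1a, a coactivator of gluconeogenesis, differed by -0.05 (SE 0.18). Cpt1a, which admits fatty acids to mitochondria, differed by -0.74 (SE 0.24, limma adjusted p = 0.246), and the hormone Fgf21 by -1.77 (SE 0.54, limma adjusted p = 0.224). Igfbp1 differed by -0.06 (SE 0.08), and the secreted hepatocyte proteins Afp and Alb by 0.01 (SE 0.08) and -0.04 (SE 0.08).

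Of 33 gene lists fixed before the data were examined, camera with a preset correlation called 14 lower and 8 higher in knockout livers. With an estimated correlation none passed, and fry, which asks whether a list's genes move one way, called 4. With 6 arrays, camera with the preset correlation called 13 lower and 8 higher, and both other tests called 0. The 4 lists that fry called with 8 arrays are described first. Each separated the array means of the groups completely (two-sided exact permutation p = 0.0286, not adjusted over the 33 lists). This is the smallest p possible with 8 arrays, and with 6 arrays it could not go below 0.1. The Dlk1-Dio3 domain list, which fry did not call, had the same exact permutation p.

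The interferon response list had a median difference of -0.71 over its 22 genes (camera adjusted p = 6.66e-16, adjusted p = 0.160 with an estimated correlation). Of these, 17 were lower when adjusted over the list alone and 1, Ifi44, over all genes tested. Oas1a, a sensor of viral RNA, differed by -0.91 (SE 0.16), the antiviral GTPase Mx2 by -0.75 (SE 0.12) and the RNA sensor Ddx58 by -0.47 (SE 0.08). With 6 arrays the median was -0.72 (fry adjusted p = 0.137), with 11 lower when adjusted over the list alone and 0 over all genes.

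Hepatocyte genes that rise after birth had a median difference of -0.40 over 24 genes (camera adjusted p = 1.97e-11, adjusted p = 0.160 with an estimated correlation). Of these, 10 were lower when adjusted over the list alone and 2, Cyp2e1 and Slco1b2, over all genes. Ugt2b1, a glucuronosyltransferase, differed by -0.81 and the amino acid catabolic enzymes Tdo2 and Tat by -1.52 (SE 0.28) and -1.09 (SE 0.17). The bile acid list had a median of -0.32 over 20 genes (camera adjusted p = 1.76e-09, adjusted p = 0.160 with an estimated correlation), with 11 lower when adjusted over the list alone and 1, Slco1b2, over all genes. Abcb11, the bile salt export pump, differed by -0.47 (SE 0.11) and Baat, which conjugates bile acids, by -0.83 (SE 0.23). Stellate cell and fibroblast markers had a median of -0.22 over 20 genes (camera adjusted p = 1.22e-06, adjusted p = 0.160 with an estimated correlation), and 7 were lower when adjusted over the list alone and 0 over all genes. Without knockout 3 and 4 the hepatocyte list had a median of -0.20 and the bile acid list of -0.21, and camera with the preset correlation still called both. With 6 arrays the medians of the hepatocyte, bile acid and stellate lists were -0.38, -0.34 and -0.22, each with a fry adjusted p = 0.137. The numbers lower when adjusted over the list alone were then 7, 1 and 0, and over all genes 1, 1 and 0.

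**Figure D3:**
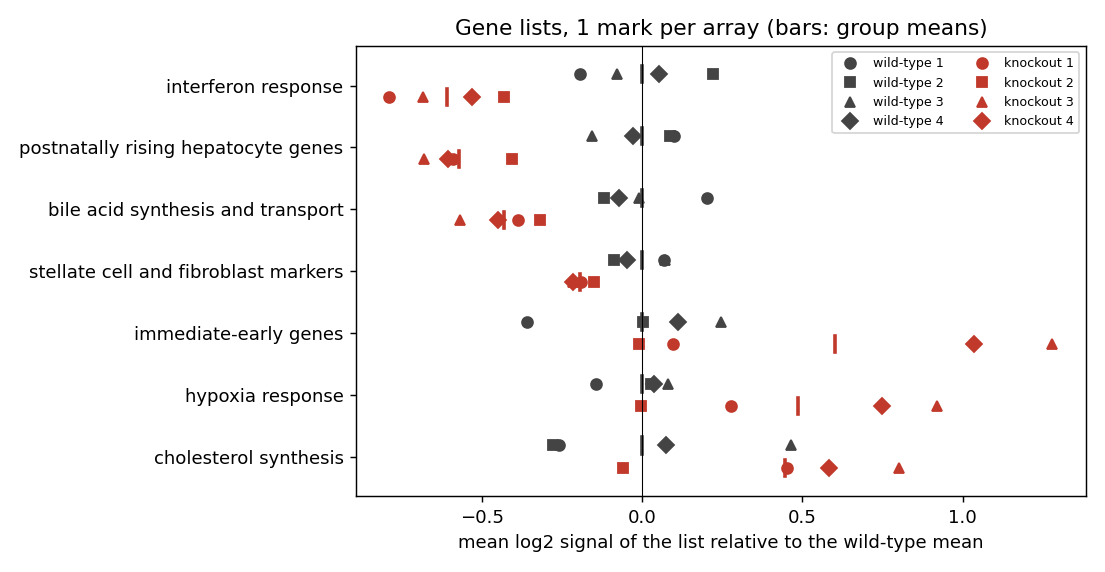
Mean log2 signal of 7 gene lists on each array, relative to the wild-type mean; 1 mark per array, grey for wild-type and red for knockout, with marker shape for the replicate number and bars for group means. In the 4 upper lists every knockout array lies below every wild-type array, and in the immediate-early list knockout 3 and 4 stand at 1.28 and 1.04 with the other 6 arrays between -0.36 and 0.25.

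The 8 lists called higher did not separate the groups. Cholesterol synthesis had a median of 0.43 and fatty acid synthesis of 0.24, with estimated-correlation adjusted p = 0.465 for both. Immediate-early genes had a median of 0.59 and hypoxia response genes of 0.31. Knockout 3 and 4 stood at 1.28 and 1.04 in the mean of the immediate-early list, and knockout 1 and 2 at 0.10 and -0.01. The same 4 arrays stood at 0.92, 0.75, 0.28 and -0.0053 in the hypoxia list and at 0.66, 0.50, 0.18 and 0.02 in the fatty acid synthesis list. Knockout 4 was close to a weighted sum of knockout 3 (0.65) and knockout 2 (0.35). The high values of knockout 3 and 4 may therefore come from 1 liver. Without knockout 3 and 4, 3 lists were called higher, namely cholesterol synthesis (median 0.21), proliferation and erythroid markers. The medians of the remaining 4 were 0.15 for glycolysis, 0.19 for the stress and unfolded protein list, 0.17 for proliferation and 0.29 for erythroid markers. Without wild-type 1 these medians were 0.09, 0.11, 0.10 and 0.13. Glycolysis and the stress list then did not pass (camera adjusted p = 0.0589 and 0.310). Without wild-type 3 and 4 those 2 lists had larger medians, of 0.25 and 0.32.

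Pancreas markers had a median of -2.40 (camera adjusted p = 0.000111, adjusted p = 0.465 with an estimated correlation), which came from wild-type 3 and 4. Relative to the wild-type mean their list means were 2.32 and 1.35, against -1.17 and -2.50 in wild-type 1 and 2 and -2.03 to -1.96 in the knockout arrays. Wild-type 4 was close to a sum in which wild-type 3 had a weight of 0.50, so this signal may come from 1 liver. Without wild-type 3 and 4, 11 genes were lower and 2 higher. The other lists called lower had medians of -0.18 for the urea cycle, -0.12 for endothelial, -0.10 for megakaryocyte, -0.18 for lymphocyte, -0.08 for macrophage and -0.10 for cholangiocyte markers, -0.07 for the acute phase, -0.05 for gluconeogenesis and -0.04 for fatty acid oxidation. With an estimated correlation their adjusted p ran from 0.448 to 0.508. Without wild-type 1 the endothelial median was -0.02 and passed, while megakaryocyte (-0.03) and macrophage (-0.06) markers did not (camera adjusted p = 0.250 and 0.450). Gluconeogenesis and the acute phase had larger falls there, of -0.10 and -0.11. With the replicate block, macrophage and cholangiocyte markers and fatty acid oxidation did not pass (camera adjusted p = 0.0912, 0.0539 and 0.0526). Without replicate 4 the lymphocyte list had a median of -0.10 and did not pass (camera adjusted p = 0.0759), and gluconeogenesis had a median of -0.03. Leaving out wild-type 1 instead gave a lymphocyte median of -0.36, which passed (camera adjusted p = 5.57e-07). Without wild-type 3 and 4 the lymphocyte list had a median of 0.05 and the pancreas list of -0.28, and neither passed. The 11 lists not called had medians of 0.02 for other imprinted genes, 0.09 for glycogen, -0.09 for PPAR-alpha targets, -0.0034 for the respiratory chain, -0.04 for the fasting response, -0.03 for the insulin axis, 0.15 for the clock, 0.00098 for fetal hepatocyte genes, 0.02 for granulocytes, -0.03 for the Dlk1-Dio3 domain and -2.24 for sex-linked genes. For fetal hepatocyte genes and granulocytes the camera direction was lower although the median lay above 0.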

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

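The tests in this part were chosen after the results were seen, except the weights of replicate 4, the random lists and the split counts without replicate 4 and of lists, whose outcomes were predicted before they were computed. Among 178 groups of 4 arrays checked, 8 had 1 array far from the other 3, and chance gives about 1 in 20. Klhl1 was -3.16 in knockout 2, below -2.83 to -2.77 in the others. Wild-type 1 stood apart in Dnah17 (-1.08), Ppargc1a (3.16), the mean of PPAR-alpha targets (-0.25) and of endothelial markers (0.25). Wild-type 3 stood apart in Col1a2 (5.83) and Col1a1 (4.32), and in the mean of sex-linked genes (-5.79). That mean held Y-linked genes only, none of which was well above background in wild-type 3. Xist, which the filter had removed, was not well above background there either.

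The first pattern is that replicate 4 of each group lay between others of its group. If RNA or cRNA of other samples had been mixed into it, weights from unrelated genes would predict its sex-linked and pancreas genes. They did, with a median absolute error of 0.170 log2 over the Y-linked and pancreas genes of wild-type 4 and of 0.136 over Xist and the Y-linked genes of knockout 4. A single male or female animal is argued against for knockout 4, where 2 Xist probes and Ddx3y were well above background. Pooling, carry-over between samples and leakage between neighbouring arrays are candidate sources that these files do not separate, and knockout 4 and wild-type 4 may therefore not be independent animals.

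With 8 arrays, 51 genes were called, and 1 of the 35 splits of the arrays, the real one, gave as many, with 2 genes at most in any other. The share cannot fall under 1 of 35, and it has this meaning only if the 8 arrays are independent. In the other splits, differences by genotype also add to the residual spread, which lowers their counts. Chance is therefore not excluded. Without replicate 4, 6 genes were called, 1 of the 10 splits gave as many, and another split called 4. That other split set the arrays with Ddx3y well above background (wild-type 1, wild-type 2 and knockout 3) against those without it. Its 4 genes may therefore reflect sex and not chance, but which genes they were was not examined. Each remaining split called 0. With 10 splits the share cannot fall under 0.1. For lists, 1 of 35 splits called as many as the real 22, but another called 19. That split exchanged 1 array of each group, wild-type 4 and knockout 2, so much of the genotype contrast remained in it. Splits with 2 arrays of each group on either side called at most 13 lists, and the cause of these calls was not tested.

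The second pattern is the lower interferon list. Fewer granulocytes, macrophages or lymphocytes as a whole would lower their markers by about as much as the list (-0.71), and their medians were 0.0209, -0.0837 and -0.181 (SD over members 0.11, 0.19 and 0.26). The lymphocyte median depended on the arrays used, with -0.36 without wild-type 1 and 0.05 without wild-type 3 and 4. A signal-dependent bias is argued against, since 0% of 10000 random lists matched on mean expression had a median as low (lowest -0.12). The stress genes of knockout 3 and 4 do not account for it, as the list mean of knockout 1 and 2 differed from wild-type by -0.61 (SD of wild-type arrays 0.18). Genotype, litter, slide column and unequal sexes stay open (arrays with Ddx3y differed by -0.63, but outside replicate 4 only knockout 3 of the knockout arrays has it), as do fewer cells of some lymphocyte type, since Cd3g differed by -0.75, Ccl5 by -0.67 and the B-cell genes Ms4a1 and Fcmr by -0.88 and -1.08 (all 4 chosen after their values were seen).

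The third pattern is the lower list of postnatally rising hepatocyte genes, for which a signal-dependent bias is argued against, as 0% of the random lists had a median as low (lowest -0.12). A lower hepatocyte share with all other cell types raised alike is argued against by the stellate list mean, which differed by -0.194 (SD of wild-type arrays 0.08). Erythroid markers had a median of 0.29 (0.13 without wild-type 1), with 23 of 26 above 0 with all arrays. Dilution by erythroid cells as the whole cause would, however, lower all hepatocyte transcripts alike. Fetal hepatocyte genes had a median of 0.00098 (SD over members 0.21) against -0.40. The list mean of knockout 1 and 2 alone differed by -0.50, and that of all knockout arrays by -0.57 (SD of wild-type arrays 0.12). This argues against stress as the whole cause. The list median was -0.20 without knockout 3 and 4, against -0.40 with them. Genotype, litter, slide column, parts played by erythroid cells and by stress in knockout 3 and 4, and unequal sexes stay open. For sex, the difference of -0.70 among arrays with Ddx3y rests on knockout 3 alone outside replicate 4.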

How the results depend on the processing

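Leaving out replicate 4 of both groups, pairs of arrays, the Xist covariate, and median centring or normexp for lists were chosen after seeing the data. With 42 genes lower and 9 higher as the main counts, the numbers lower and higher were 66 and 14 under quantile normalization, 117 and 23 under normexp with quantile, 123 and 21 with the median signal and quantile, 120 and 21 with the authors' value table, 19 and 0 without a filter, 119 and 30 with trend and robust, and 17 and 0 at an adjusted p under 0.01. They were 78 lower with Ddx3y as a covariate, 15 and 3 with Xist, 11 and 2 without wild-type 3 and 4, and 9 and 3 without knockout 3 and 4. Of the 51 main calls, 8 passed with the Xist covariate and 45 with the Ddx3y covariate. Array weights gave 1480 and 1640, with weights of 3.34 for wild-type 4 and 4.23 for knockout 4. Those are the arrays that may be sums of others, so this count was not used. Without both replicate 4 arrays the counts were 6 and 0. Leaving out 1 array gave 14 to 66 lower and 0 to 24 higher, with 66 and 24 without wild-type 1, 20 and 0 without wild-type 2, 19 and 1 without wild-type 3, 18 and 3 without wild-type 4, 27 and 3 without knockout 1, 18 and 1 without knockout 3, and 14 and 0 without knockout 4. The 51 genes kept their direction in each of these fits where they were tested. For the fits that only left out arrays this was certain, because each of the 51 separated the groups completely. Other causes of these shifts were not tested. No spot was saturated, so that alternative removed nothing.

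With the replicate block, 17 genes were lower and 2 higher, and 14 of the 51 main calls passed. Same-numbered arrays did not deviate together in every pair (r over genes from -0.11 to 0.07). These values cannot show whether same-numbered samples shared a litter or a batch. The number is also the row on the slide.

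Lists called lower and higher were 14 and 8. They were 0 and 0 with an estimated correlation, and 4 and 0 with fry. The number higher was 3 without knockout 3 and 4, and the number lower was 9 with the Xist covariate. The test direction of the granulocyte list turned, with medians of 0.021 under fry, without a filter and with the replicate block, 0.049 without replicate 4, 0.11 without wild-type 3 and 4, -0.029 with the Xist covariate, and -0.069 to 0.080 when 1 array was left out. It also turned for immediate-early genes (median 0.00310) and the clock (0.0546) without knockout 3 and 4, for sex-linked genes without a filter (-0.69) and with Xist (3.67), and with Xist for fetal hepatocyte genes (0.000288) and cholangiocytes (-0.11). None of these was called on both sides. G6pc was -0.00680 under normexp with quantile and Ppargc1a 0.032 without replicate 4. Leaving out 1 array gave -0.12 to 0.13 for G6pc, -0.041 to 0.056 for Afp, -0.23 to 0.018 for Ppargc1a, -0.10 to 0.00918 for Alb and -0.087 to 0.25 for Dio3. Pck1, Oas1a, Mx2, Ddx58, Tat, Col1a2 and Kmo passed with normexp and quantile together, and of these Ddx58 and Tat with quantile alone. Under normexp and quantile together Tcp10b (0.25) and Spata17 (0.12) no longer passed, nor did Spata17 in the authors' table (0.14), and the values of Cfc1, Myl1, Ptprz1 and Klhl1 shrank by over 1.5 times. Dim probes limit the bounds given for Cfc1 and Tcp10b.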

Other observations

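The called genes given here lie outside the fixed lists and were chosen after their values were seen. Abcg8, the partner of Abcg5, differed by -1.22 (limma adjusted p = 0.0375), and the aldo-keto reductase Akr1c20 by -1.43 (adjusted p = 0.00178). Bhmt, an enzyme of methionine metabolism, differed by -1.06 and the cytochromes Cyp2j9, Cyp2j8 and Cyp2j6 by -1.09, -1.10 and -0.65. Interferon-induced genes outside the list, Oasl1, Rtp4 and Ifi27, differed by -1.31, -0.78 and -0.60. All passed a limma adjusted p of 0.05 with 8 arrays, and none did without replicate 4.

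Wild-type 3 had Ddx3y at -7.67 and its Xist probes at -6.55 and -7.78, none well above background. Ddx3y was 2.21 in wild-type 1 and 2.21 in wild-type 2, and the second of these Xist probes was 1.72 in knockout 1 and 1.52 in knockout 2. No wild-type array had Xist well above background.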
